A study of Ovis aries with 16 samples.

How the data were processed

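RNA sequencing measured gene expression in fat of female sheep, in 16 libraries that fall into 4 groups of 4: visceral control, visceral bisphenol A (BPA), subcutaneous control and subcutaneous BPA. Replicates are named by the number that opens each title. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with a low-input kit.

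Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and MultiQC 0.9, aligned with STAR 2.6.0c and counted per gene with featureCounts of Subread 1.6.1. The deposited table holds 1 count per gene and library for 28524 genes. Its name calls the values normalized, but 0 of its values are other than whole numbers and the library totals differ from 3046126 to 14305764, so the values were treated as raw counts. The genome build, the annotation and the strand setting are not given in the sources used here. Gene types were taken from a reference table of the ARS-UI_Ramb_v3.0 sheep annotation, which was joined by symbol or gene number. The deposited table also holds a column of gene lengths, and genes without a match had a length too. The join matched 22708 genes and left 5816 unmatched, and 406 of 10441 LOC identifiers received a symbol. No positions are given, since the build behind the counts is unknown.

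Genes were filtered with filterByExpr at its default settings (a count of 10 at the median depth, 15 in total), scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided). R was version 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. The comparisons were BPA against control in each depot, visceral against subcutaneous fat in control animals and in BPA animals, each on 8 libraries, and the difference between both BPA effects on all 16. Values are CPM, the counts over the TMM-scaled library total, given as mean ± SD with n = 4, and log2 fold changes carry their standard error (SE). Standard errors were derived from the estimate and the test. The genes named were chosen by a rule fixed before the data were examined. It takes the 8 highest and the 8 lowest called changes without overlap between groups, or the 10 smallest p where fewer than 10 genes were called. It adds up to 4 members of each fixed list with the smallest p, and PPARG, ADIPOQ, LEP, FASN, SCD, UCP1, ESR1, INSR, CD68 and COL1A1. UCP1 had too few counts to be tested in any comparison. Called genes without a symbol are named only for the 2 largest rises and the 2 largest falls, and the text gives values for part of the genes the rule names.

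The comparisons, tests, gene lists and alternatives were also fixed before the data were examined, except where the text says otherwise. The 33 fixed lists cover lipid storage, fatty acid and cholesterol synthesis, thermogenic fat, insulin signalling, oxidative stress defence, steroid receptors, extracellular matrix, interferon, cytokines, circadian clock, chromatin enzymes, cell cycle, protein and RNA machinery, depot developmental genes and markers of other cell types. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, on log2 CPM with a prior count of 2, two-sided, with Benjamini-Hochberg adjustment over the lists with at least 5 tested members. Each list was tested again with an estimated correlation. The mitochondrial genome list had 0 members in the table. The epithelial, histone and red blood cell lists had at most 4 tested members in each comparison and were not tested, nor was the mesothelial list in subcutaneous fat. The 2 lists of snoRNA and snRNA genes were defined by gene type or name pattern. A list score per library is the median, over members, of log2 CPM centred on the mean of the 16 libraries, and scores were compared with exact two-sided permutation tests of 4 against 4 libraries. These scores, the measures per library, the test of gene types and the overlap of depot differences were added after the data were seen.

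Alternatives were DESeq2 1.42.0 as the test, its size factors in place of TMM, quantile normalization, no filter and a filter of 50 counts in 4 libraries. Others were library weights, robust moderation, a threshold of 0.10, a fit of all 16 libraries, the title number as a block, and omission of each library in turn. Alternatives chosen after seeing the data were thinning of every library to the lowest total, limma voom without a block, omission of subcutaneous controls 902 and 924 together, omission of genes under 200 bases, and the library total as a covariate.

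The number in the title was checked as an animal identifier, by the correlation across genes of each library's deviation from its group mean. For the 3 control numbers found in both depots the correlation was 0.287, 0.40 and 0.332, and each library matched its own number best, so these were taken as pairs. For the 2 BPA numbers it was 0.167 and 0.031. Both libraries of 918 matched each other best, while visceral 977 matched subcutaneous 941 better (0.11), so whether these are pairs is open. The comparisons of depots therefore hold related libraries, and the block is given beside the control result.

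The tests were tested on simulated data with the libraries' own depth and spread. For 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 33% and 77% in visceral BPA against control, and 49% and 88% in the subcutaneous comparison. It recovered 41% and 91% between depots in controls, 25% and 93% in BPA animals, and 11% and 66% for the difference between BPA effects. Unchanged genes made up 4.8% to 7.6% of its calls, against 13.9% to 17.6% for DESeq2. The camera test found the 1 changed list in all 5 comparisons and called 0 of 19 unchanged lists. The simulated genes vary independently, so this is no false-call rate for the preset correlation in real libraries. Other splits of these called 3 to 14 lists in the visceral and 4 to 13 in the subcutaneous BPA comparison. Intervals and floors cover counting error only, because no molecular identifiers mark the reads. Where a group had no count, the fold was computed against a floor of 3 counts over the group. Genes of tRNA, snRNA, snoRNA and ribosomal RNA families have near-identical copies, so the count of any single copy is uncertain.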

Results

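The fat came from ewes 21 months old whose mothers had received bisphenol A, a plastics chemical that can act on oestrogen receptors, or corn oil alone. BPA was given at 0.5 mg/kg/day from day 30 to day 90 of a gestation of 147 days. Visceral fat was mesenteric and subcutaneous fat was sternal, and both were taken 24 hours after the last of a pair of prostaglandin injections that synchronized the cycle. Each of the 4 groups has 4 libraries, and 5 animal numbers occur in both depots. Totals in subcutaneous fat were 6.22, 5.27, 6.19 and 4.74 M counts in controls 902, 924, 928 and 931. They were 4.83, 4.31, 3.05 and 4.35 M in BPA replicates 918, 922, 941 and 977. Visceral totals were 11.6, 11.0, 12.04 and 13.1 M in controls 902, 908, 924 and 928, and 9.60, 9.04, 6.77 and 14.31 M in BPA replicates 910, 918, 977 and 984. Subcutaneous BPA libraries were shallower than their controls (4.13 ± 0.762 against 5.61 ± 0.728 M, SD, n = 4; exact two-sided permutation p = 0.0571).

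Depot was the main division of the libraries. The first principal component held 32.8% of the variance, with visceral libraries from -51.6 to -27.7 and subcutaneous ones from 18.7 to 69.5. The next component (14.7%) set visceral BPA replicate 977 apart at -95.6. The third (10.7%) set subcutaneous controls 902 and 924 apart at 53.5 and 51.9.

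**Figure D1:**
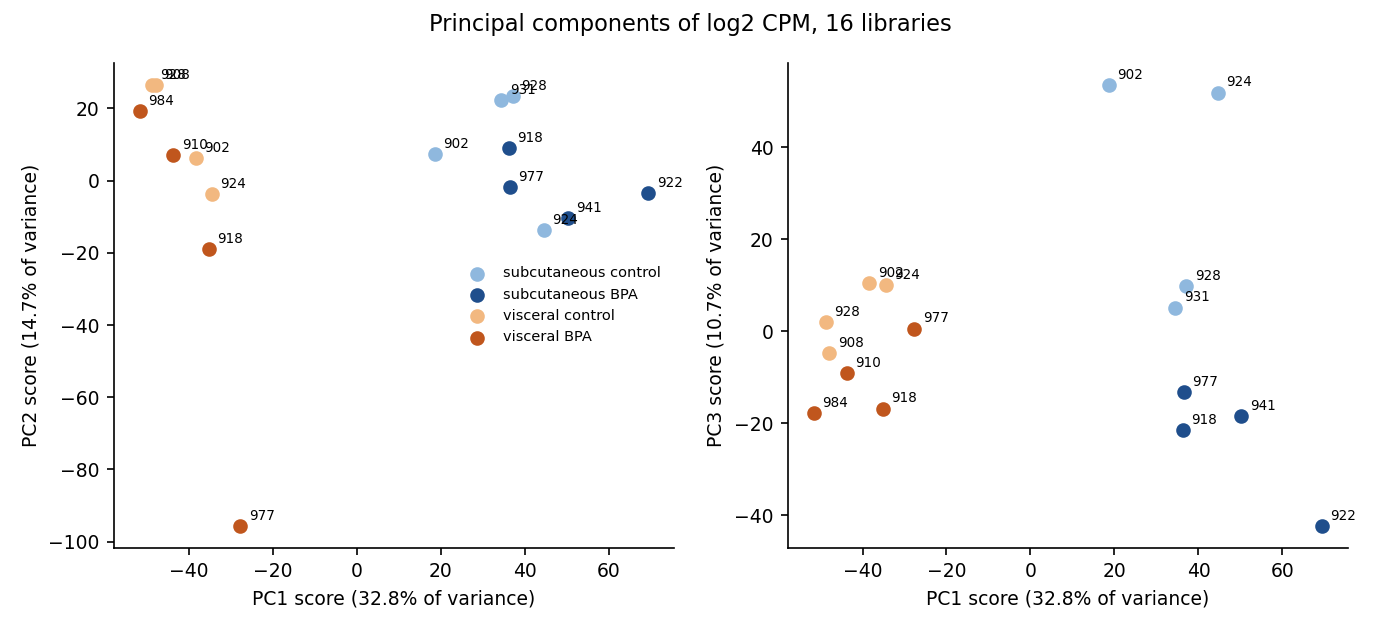
Principal component scores of log2 CPM for the 16 libraries, with the percent of variance on each axis. Points are libraries with their animal number, coloured by group. Visceral BPA replicate 977 lies at -95.6 on the second component, and subcutaneous controls 902 and 924 lie at 53.5 and 51.9 on the third.

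The comparison of BPA with control in subcutaneous fat asks which genes prenatal exposure left changed in the adult depot. Part of the snoRNA (42 of 141) and snRNA genes (10 of 20) rose, though neither list passed with an estimated correlation (adjusted p = 0.234 and 0.118), and 14 genes fell, C5AR1, TYROBP, FN1 and THY1 among them. Of 13535 genes tested, 82 rose and 14 fell (edgeR quasi-likelihood, Benjamini-Hochberg), and 72 of the 82 are shorter than 200 bases. With genes under 200 bases left out of the test, 1 gene was called higher and 0 lower, so no fall was called there. Of the snoRNA genes, guides of chemical modification of ribosomal RNA, 42 of 141 rose and 0 fell. Of the snRNA genes, the RNA core of the splicing machinery, 10 of 20 rose. Ribosomal RNA genes (7 of 10) and tRNA genes (4 of 15) also held more rises than other genes (Fisher's exact adjusted p = 4.1e-14 and 1.94e-06). The total share of ribosomal RNA genes overlapped between groups (0.302 ± 0.0680 against 0.254 ± 0.0770%, exact two-sided permutation p = 0.371). Genes in 1 family are not independent, and any single copy is uncertain. Genes shorter than 200 bases took 0.991 ± 0.329% of counts in BPA libraries and 0.386 ± 0.0492% in controls (SD, n = 4 each). All 4 BPA libraries lay above all 4 controls (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow; Benjamini-Hochberg 0.103 over 36 library measures). Of the 202 short genes tested, 148 were classed as inside a longer gene, a class that is uncertain because the build is unknown. The strand of counting is not given, so their reads cannot be told from those of the host gene.

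Among single genes, the unmatched short gene LOC114112289 rose 13.7-fold (log2 3.78 ± 0.33 SE; 156 ± 65.3 against 11.3 ± 3.22 CPM; adjusted p = 0.00118). The lysine tRNA gene TRNAK-CUU_8 rose 6.37-fold (adjusted p = 0.0081), TRNAM-CAU_7 7.33-fold (0.0181) and TRNAR-CCU_7 7.27-fold (0.0394), each a family of like copies. MIR143, a microRNA gene of smooth muscle, rose 3.24-fold (adjusted p = 0.0476). CNTD2, a cyclin-like gene, rose 3.89-fold from 9.82 ± 1.83 to 38.3 ± 9.40 CPM (adjusted p = 0.00476). MLXIPL, the carbohydrate-responsive regulator of fat synthesis, rose 2.62-fold from 37.8 ± 6.36 to 99.2 ± 22.8 CPM (log2 1.39 ± 0.19; adjusted p = 0.00868). LMOD1, a nucleator of smooth muscle actin, rose 2.46-fold (adjusted p = 0.043). C5AR1, the complement C5a receptor of myeloid cells, fell by 1.33 ± 0.18 on the log2 scale, from 39.5 ± 4.42 to 15.7 ± 3.13 CPM (adjusted p = 0.00868). TYROBP, a signalling adaptor of myeloid cells, fell by 1.75 ± 0.33 (adjusted p = 0.0447), SRGN, a granule proteoglycan of blood cells, by 1.66 ± 0.29 (0.0318), and UBASH3B, a phosphatase, by 1.62 ± 0.32 (0.049). FN1, the matrix glycoprotein fibronectin, fell by 1.67 ± 0.31 from 598 ± 259 to 188 ± 50.7 CPM (adjusted p = 0.0396; -1.001 on the log2 scale without controls 902 and 924), and THY1, a surface protein of stromal cells, by 1.03 ± 0.19 (0.0429). RAB27B (vesicle transport), HPCAL4 (a calcium sensor), DSP (desmoplakin) and LOC101102413 also fell, by 1.38, 2.38, 1.47 and 1.74.

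The 14 genes that fell and the 5 protein-coding genes that rose are few among 12157 tested. Of 28 fixed lists, 14 were called at the preset correlation and 0 with an estimated one (smallest adjusted p 0.118). All 18 macrophage and monocyte markers had lower estimates, with a median log2 fold change of -0.985 (camera adjusted p = 2.3e-15, adjusted p = 0.148 with an estimated correlation). TYROBP alone of them fell over all genes tested, and 16 fell adjusted over the list alone. CD68, a lysosomal protein of macrophages, had 22.9 ± 2.12 against 45.7 ± 23.9 CPM (adjusted p = 0.179), and C1QA, a complement component, 41.9 ± 7.78 against 82.1 ± 19.5 (0.0578). All 11 lymphocyte markers were lower (median -1.11; adjusted p = 8.57e-06, and adjusted p = 0.408 with an estimated correlation), with 0 called and 7 adjusted over the list alone. Lymphocyte scores were 1.258 and 0.721 in controls 902 and 924 but 0.01 and -0.063 in 928 and 931, below BPA 941 at 0.286. The median was -0.315 without 902 and 924 (-1.346 to -0.315 over the alternatives). PTPRC, the leukocyte surface phosphatase CD45, had 63.3 ± 22.7 against 136 ± 70.8 CPM (log2 -1.113, and -0.353 without 902 and 924; adjusted p = 0.208). Extracellular matrix genes had a median of -0.48 (adjusted p = 7.14e-06, adjusted p = 0.408 with an estimated correlation), with 1 of 25 lower and 9 adjusted over the list alone. COL1A1, fibrillar collagen, had 863 ± 295 against 1851 ± 323 CPM (adjusted p = 0.0622). Adipose progenitor markers had a median of -0.57 (adjusted p = 0.00208, adjusted p = 0.408 with an estimated correlation), 1 of 15 lower and 4 adjusted over the list alone.

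At the preset correlation only, adipocyte and smooth muscle lists were called higher. Adipocyte genes were higher in 23 of 25, by a median of 0.27 (adjusted p = 0.00538, adjusted p = 0.464 with an estimated correlation), with 0 called on either adjustment. AQP7, the glycerol channel of fat cells, had 348 ± 54.4 against 208 ± 70.3 CPM (adjusted p = 0.179), and SLC2A4, the insulin-responsive glucose transporter, 41.7 ± 11.8 against 25.0 ± 4.90 (0.18). Smooth muscle markers had a median of 0.29 (adjusted p = 0.00558, adjusted p = 0.409 with an estimated correlation), 1 of 13 called and 2 adjusted over the list alone. Circadian clock genes had a median of 0.23 (adjusted p = 0.0224, adjusted p = 0.464 with an estimated correlation) and 0 called. The snoRNA list had a median of 1.48 (adjusted p = 9.18e-62, adjusted p = 0.234 with an estimated correlation; 118 adjusted over the list alone). The snRNA list had 1.68 (5.42e-16, adjusted p = 0.118 with an estimated correlation; 14 adjusted over the list alone). Lower lists with 0 genes called were ribosomal proteins (-0.23, adjusted p = 5.31e-07, adjusted p = 0.509 with an estimated correlation) and oxidative stress defence (-0.24, 0.00538, adjusted p = 0.464 with an estimated correlation). So were cytokines (-0.26, 0.0054, adjusted p = 0.408 with an estimated correlation), immediate early genes (-0.22, 0.00944, adjusted p = 0.508 with an estimated correlation) and endothelial markers (-0.25, 0.0265, adjusted p = 0.464 with an estimated correlation; 1 adjusted over the list alone).

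The other 14 lists were not called in subcutaneous fat (adjusted p from 0.0781 to 0.832). They are endoplasmic reticulum stress, skeletal muscle, fatty acid synthesis, thermogenic fat, cholesterol synthesis, interferon, depot developmental genes, nerve, steroid receptors, insulin signalling, proteasome, chromatin enzymes, cell cycle and respiratory chain. Median and mean differed in sign for insulin signalling (0.012 and -0.102) and chromatin enzymes (0.03 and -0.005). Of the genes named whatever their result, PPARG, the master regulator of fat cells, had log2 0.23 ± 0.13 (adjusted p = 0.44), ADIPOQ (adiponectin) 0.02 ± 0.31 (0.983) and LEP (leptin) -1.29 ± 0.51 (0.293). Control 902 lay apart from its group in LEP, at 562.434 CPM when scaled over 16 libraries. FASN (fatty acid synthase) had 0.41 ± 0.39 (0.678), SCD (stearoyl desaturase) -0.45 ± 0.77 (0.837), ESR1 (oestrogen receptor) 0.26 ± 0.26 (0.685) and INSR (insulin receptor) 0.22 ± 0.14 (0.52).

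The subcutaneous count of 96 rested on several libraries. It was 32 without control 902, 34 without control 924, 56 without control 928, 37 without BPA 922 and 48 without BPA 941. Without controls 902 and 924 together it was 0 for edgeR, an alternative chosen after seeing the data that leaves 2 controls. It was 1 when genes under 200 bases were left out (CNTD2), and MLXIPL and every fall, C5AR1 included, were then not called. The count was 13 with the library total as a covariate, 1 by limma voom on all 16 libraries and 464 by DESeq2, all on the same subcutaneous comparison. DESeq2 called 251 higher and 213 lower, and the edgeR fit of all 16 libraries 29 and 17, so falls were a larger part there. At an unadjusted p under 0.05 there were 1926 genes where 677 would be expected. All 96 called genes had no overlap between groups, as had 7.4% of all genes tested against a chance share of 2.86%. Of 18 called genes named here, LOC114112289, CNTD2, TRNAK-CUU_8, MLXIPL and C5AR1 were called in every omission of 1 library. The other 13 each missed the threshold in at least 1. Omission of control 902, 924, 928 or 931 ended 13, 13, 4 and 5 of the 18 calls (highest adjusted p 0.164, 0.0907, 0.0991 and 0.0717), and of BPA 918, 922, 941 or 977 it ended 8, 13, 9 and 12 (0.133, 0.143, 0.108 and 0.104).

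Some list calls in subcutaneous fat were also lost when 1 library was left out. The endothelial call was lost without control 902 (adjusted p = 0.224), control 928 (0.0546), BPA 918 (0.114), BPA 922 (0.0903) or BPA 941 (0.0524). The adipocyte call was lost without control 924 (0.0982), BPA 918 (0.122) or BPA 977 (0.0663), and the smooth muscle call without control 924 (0.0701). The clock call was lost without control 902 (0.0572, median 0.154) or BPA 922 (0.161, median 0.064), and the oxidative stress call without BPA 941 (0.109). The immediate early call was lost without control 928 (0.0675, median -0.119), BPA 922 (0.108, median -0.057) or BPA 941 (0.089, median -0.07). The macrophage, lymphocyte, matrix, progenitor, ribosomal protein, cytokine, snoRNA and snRNA calls passed in every such omission. Without controls 902 and 924 together, 10 of the 14 list calls remained, and the adipocyte (0.3), clock (0.107), endothelial (0.181) and cytokine (0.0819) calls were lost. In scores per library, macrophage markers of the 4 BPA libraries lay below all 4 controls (exact two-sided permutation p = 0.0286; Benjamini-Hochberg 0.166 over 29 lists).

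**Figure D2:**
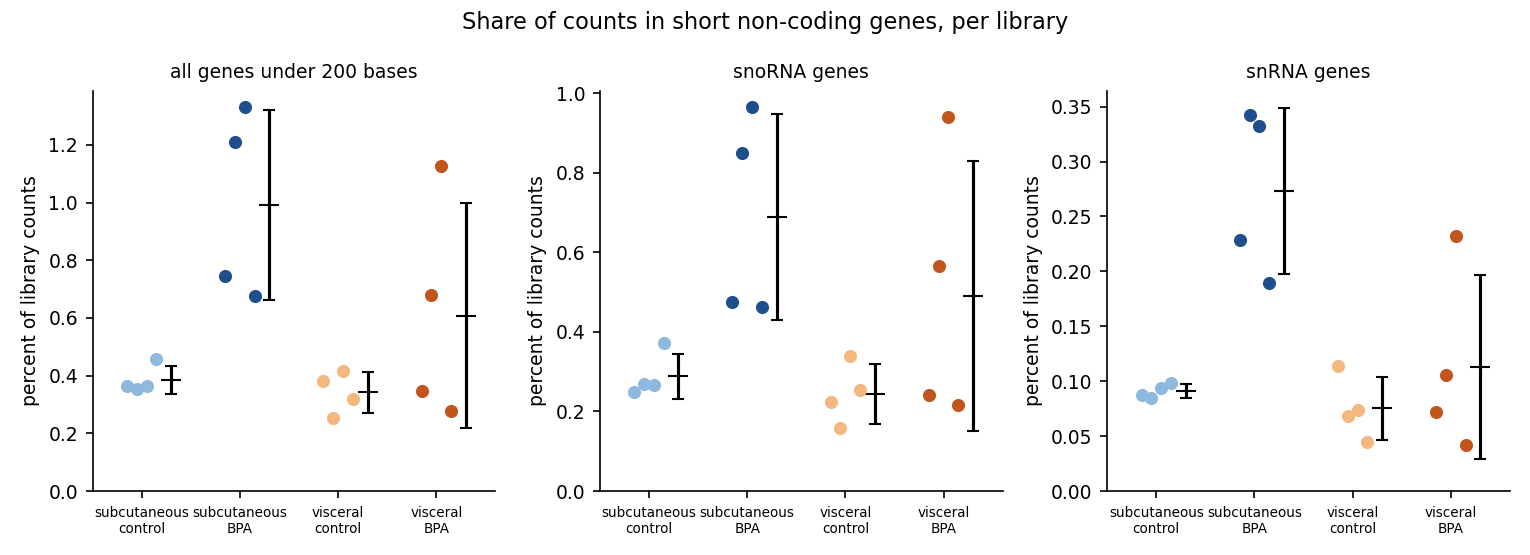
Percent of each library's counts in genes under 200 bases, in snoRNA genes and in snRNA genes. Points are libraries and bars are group means with SD (n = 4). In subcutaneous fat the BPA libraries lie between 0.676% and 1.33% for genes under 200 bases, above controls at 0.355% to 0.459%.

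In visceral fat, the same comparison called no gene. The snoRNA list was higher at the preset correlation, though not with an estimated one (adjusted p = 0.809), and 2 of 4 BPA libraries scored within the controls. edgeR called 0 of 14774 genes, with 1103 at an unadjusted p under 0.05 where 739 would be expected. DESeq2 called 5 (2 higher, 3 lower), and limma voom on all 16 libraries, with or without the block, called 0. The smallest adjusted p was 0.658, shared by the 10 genes of smallest p that follow. DDR2, a collagen receptor, had 178 ± 22.5 against 295 ± 28.5 CPM (log2 -0.73 ± 0.15, SE, n = 4), and MFAP5, a microfibril protein, 30.2 ± 2.95 against 56.2 ± 12.7. ARSD (LOC101116024), an arylsulfatase, had 43.5 ± 18.3 against 17.0 ± 4.54 CPM, and SAMD11 23.6 ± 4.59 against 12.97 ± 0.828. C4BPA and C7, complement proteins, had log2 -1.74 ± 0.39 and -1.15 ± 0.26. PSTPIP2, a cytoskeletal adaptor, had -1.36 ± 0.32, DGAT1, which makes triglyceride, 0.80 ± 0.19, ARID3A, a transcription factor, 0.89 ± 0.21 and NFKBIA, an inhibitor of NF-kappaB, 0.73 ± 0.17. Of all genes tested, 601 (4.07%) had no overlap between groups, against a chance share of 2.86%.

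Of the visceral lists, 6 of 29 were called. The snoRNA genes were higher in 153 of 171, by a median of 0.94 (camera adjusted p = 2.16e-17, adjusted p = 0.809 with an estimated correlation), with 0 genes called, also when adjusted over the list alone. Their share was 0.491 ± 0.339% of counts against 0.244 ± 0.0749% (SD, n = 4; exact two-sided permutation p = 0.286), and 0.342 ± 0.195% without BPA 977, which had 0.9405%. The list scores of BPA 910 and 984 (-0.302 and -0.606) lay within those of controls (-0.922 to -0.036), below BPA 918 and 977 (0.686 and 1.142). Chromatin and DNA methylation enzymes had a median of 0.19, higher in 22 of 25 (adjusted p = 0.00883, adjusted p = 0.809 with an estimated correlation). UHRF1, which maintains DNA methylation, had 8.66 ± 10.5 against 2.63 ± 1.22 CPM, and HDAC1, a histone deacetylase, 145 ± 34.2 against 111 ± 8.28. The UHRF1 mean rests on BPA 977, with 25.29 CPM against 2.485 to 4.441 in the other 3 when scaled over 16 libraries. Smooth muscle markers had a median of 0.44 (adjusted p = 0.0299, adjusted p = 0.809 with an estimated correlation), with MYH11, smooth muscle myosin, at 812 ± 895 against 262 ± 205 CPM, a mean that rests on BPA 918. Respiratory chain genes were lower in 54 of 68, by a median of -0.16 (adjusted p = 0.00151, adjusted p = 0.809 with an estimated correlation). Ribosomal proteins had -0.19 (adjusted p = 0.00883, adjusted p = 0.875 with an estimated correlation). Adipose progenitor markers had -0.16 (adjusted p = 0.0299, adjusted p = 0.809 with an estimated correlation), with 2 lower adjusted over the list alone. PI16, a marker of early progenitors, had 13.9 ± 3.38 against 28.5 ± 10.8 CPM.

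The remaining visceral lists were not called (adjusted p from 0.0614 to 0.964). They are oxidative stress, endothelial, proteasome, interferon, macrophage, lymphocyte, steroid receptor, immediate early, nerve, insulin signalling, thermogenic, cell cycle, clock, mesothelial, adipocyte, matrix, snRNA, endoplasmic reticulum stress, cholesterol, cytokine, fatty acid synthesis, depot developmental and skeletal muscle genes. For 4 of them the median and the direction of the test differed in sign. These were mesothelial (median 0.38, mean 0.234, test lower), matrix (0.03, 0.11, lower), snRNA (-0.014, 0.032, higher) and fatty acid synthesis (-0.054, 0.022, higher). Without BPA 918, 10 lists were called. Without BPA 977 the respiratory chain (adjusted p = 0.46), ribosomal (0.954) and chromatin (0.0892) calls were lost. The ribosomal (0.576) and smooth muscle (0.101) calls were lost without control 908, and the smooth muscle call without BPA 918 (0.295) or 984 (0.0846). The progenitor call was lost without control 924 (0.156), BPA 910 (0.128) or BPA 984 (0.0846), and with the replicate block on 16 libraries (0.109). The snoRNA call passed in every omission. PPARG had log2 -0.06 ± 0.25 (adjusted p = 0.943), ADIPOQ -0.28 ± 0.23 (0.74), LEP -0.76 ± 0.53 (0.701; -1.594 without BPA 910), FASN -0.34 ± 0.36 (0.787) and SCD -0.08 ± 0.28 (0.938). ESR1 had -0.24 ± 0.29 (0.803), INSR -0.09 ± 0.23 (0.912), CD68 0.09 ± 0.18 (0.884) and COL1A1 1.06 ± 0.56 (0.658). The COL1A1 value rests on BPA 977 and was 0.151 without it.

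**Figure D3:**
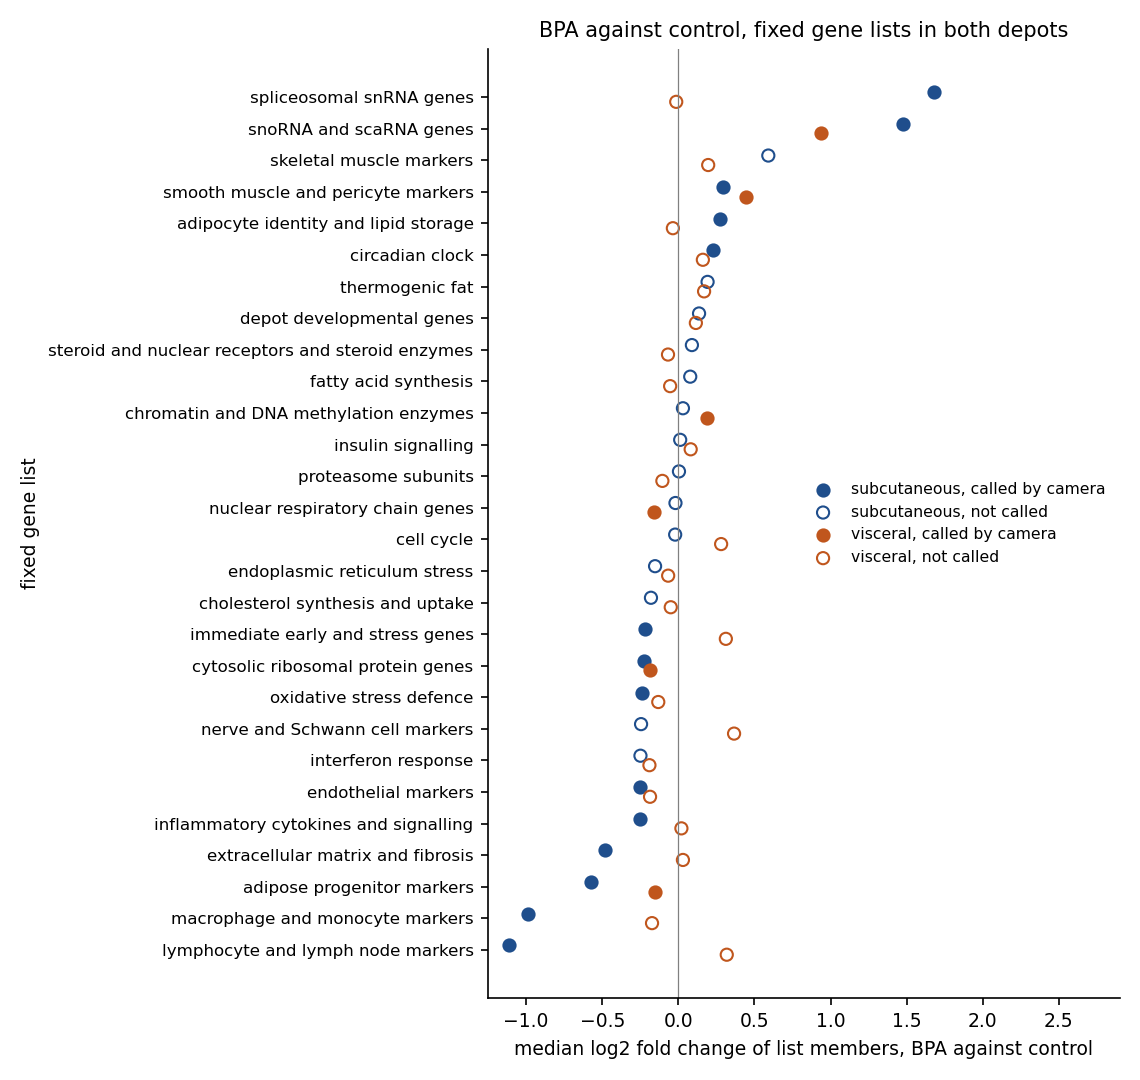
Median log2 fold change of BPA against control over the members of each fixed list tested in subcutaneous fat, in subcutaneous (blue) and visceral (orange) fat. Filled points were called by camera at its preset correlation. In subcutaneous fat the medians run from -1.11 for lymphocyte markers to 1.68 for snRNA genes.

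Whether the BPA effect differed between depots was tested on all 16 libraries. No single gene passed. Macrophage, lymphocyte, cytokine and matrix lists had a higher visceral than subcutaneous effect at the preset correlation, while 0 lists were called with an estimated correlation (smallest adjusted p 0.0972). edgeR called 0 of 14793 genes, with 917 at an unadjusted p under 0.05 where 740 would be expected. DESeq2 called 11 (3 higher, 8 lower), and limma voom called 0. The smallest adjusted p, 0.649, was shared by the genes of smallest p. They include CNTD2 (log2 difference -1.88 ± 0.36), BMP5, a bone morphogenetic protein (-1.48 ± 0.32), UBASH3B (1.77 ± 0.42), ACAD8, an enzyme of valine breakdown (-1.18 ± 0.28), TBC1D10C (2.69 ± 0.64), FMOD, fibromodulin (2.39 ± 0.58) and SHANK1, a scaffold protein (4.60 ± 1.08). TYROBP had 1.56 ± 0.42 and FN1 2.96 ± 0.82. Without visceral BPA 977, FN1 had 1.476 and SHANK1 3.367. Of the lists, 11 of 29 were called. All 18 macrophage markers had a higher visceral than subcutaneous effect (median difference 0.89; camera adjusted p = 7.79e-12, adjusted p = 0.0972 with an estimated correlation), with 0 genes called and 6 adjusted over the list alone. All 18 lymphocyte markers did so too (1.46; adjusted p = 1.63e-09, adjusted p = 0.298 with an estimated correlation). Their median was 0.675 without subcutaneous controls 902 and 924 and 1.077 without visceral BPA 977 (0.675 to 1.757 over the alternatives). Other lists with a higher visceral effect were matrix (0.35, 0.000218, adjusted p = 0.362 with an estimated correlation; 3 adjusted over the list alone) and immediate early genes (0.645, 0.000331, adjusted p = 0.566 with an estimated correlation). Cytokines had 0.41 (0.000543, adjusted p = 0.172 with an estimated correlation).

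Lists with a lower visceral than subcutaneous effect were led by short RNAs. The snRNA genes had a median difference of -0.96 (adjusted p = 3.09e-11, adjusted p = 0.0972 with an estimated correlation; 3 adjusted over the list alone). The snoRNA genes had -0.57 (adjusted p = 2.81e-12, adjusted p = 0.566 with an estimated correlation; 1 adjusted over the list alone). Adipocyte genes had -0.30 (0.000511, adjusted p = 0.566 with an estimated correlation), respiratory chain genes -0.16 (0.00314, adjusted p = 0.632 with an estimated correlation), proteasome subunits -0.12 (0.011, adjusted p = 0.632 with an estimated correlation) and steroid receptors -0.15 (0.0429, adjusted p = 0.362 with an estimated correlation). The other 18 lists were not called (adjusted p from 0.0569 to 0.83). They are nerve, chromatin, skeletal muscle, progenitor, insulin signalling, cell cycle, ribosomal protein, fatty acid synthesis, clock, endoplasmic reticulum stress, cholesterol, depot developmental, oxidative stress, endothelial, smooth muscle, thermogenic, interferon and mesothelial. Median and test differed in sign for cholesterol (-0.008, mean 0.182, higher), thermogenic (0.033, mean 0.052, lower), interferon (0.063, mean 0.026, lower) and mesothelial genes (0.523, mean 0.48, lower). COL1A1 had a difference of 2.16 ± 0.67 (adjusted p = 0.649; 1.262 without visceral BPA 977), CD68 1.09 ± 0.37 (0.705), LEP 0.52 ± 0.82 (0.999, and -0.06 without subcutaneous control 902), SCD 0.37 ± 0.92 (0.999) and FASN -0.75 ± 0.59 (0.971). PPARG had -0.29 ± 0.29 (0.996), ADIPOQ -0.30 ± 0.41 (0.999), INSR -0.31 ± 0.28 (0.982) and ESR1 -0.51 ± 0.41 (0.977).

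Several of these list calls for the difference were lost when 1 library was left out. The proteasome call was lost without visceral control 908 (adjusted p = 0.167), visceral control 928 (0.0548), visceral BPA 918 (0.069), visceral BPA 977 (0.347) or subcutaneous BPA 918 (0.0695). It was also lost without subcutaneous control 924 (0.659), where its median was 0.017. The respiratory chain call was lost without visceral BPA 977 (0.509), subcutaneous control 924 (0.453) or subcutaneous BPA 918 (0.0695). The steroid receptor call was lost without visceral controls 902 (0.0607), 924 (0.0791) or 928 (0.0634), visceral BPA 977 (0.134) or 984 (0.113), subcutaneous control 931 (0.0565), or subcutaneous BPA 918 (0.0695) or 977 (0.0764). The other 8 calls passed in every omission of 1 library, but the adipocyte call was lost without subcutaneous controls 902 and 924 together (0.123). Across 13389 genes, the log2 effects of BPA in both depots had a Pearson r of 0.282, and genes are not independent replicates. With animals relabelled, the median r was 0.123 and the range -0.205 to 0.388, and 16 of 95 labellings gave an r as high. It was 0.111 with the visceral effect from animals sampled in that depot only, control 908 against BPA 910 and 984. With the subcutaneous effect from control 931 against BPA 922 and 941, sampled there only, it was 0.24. Each rests on 1 control.

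**Figure D4:**
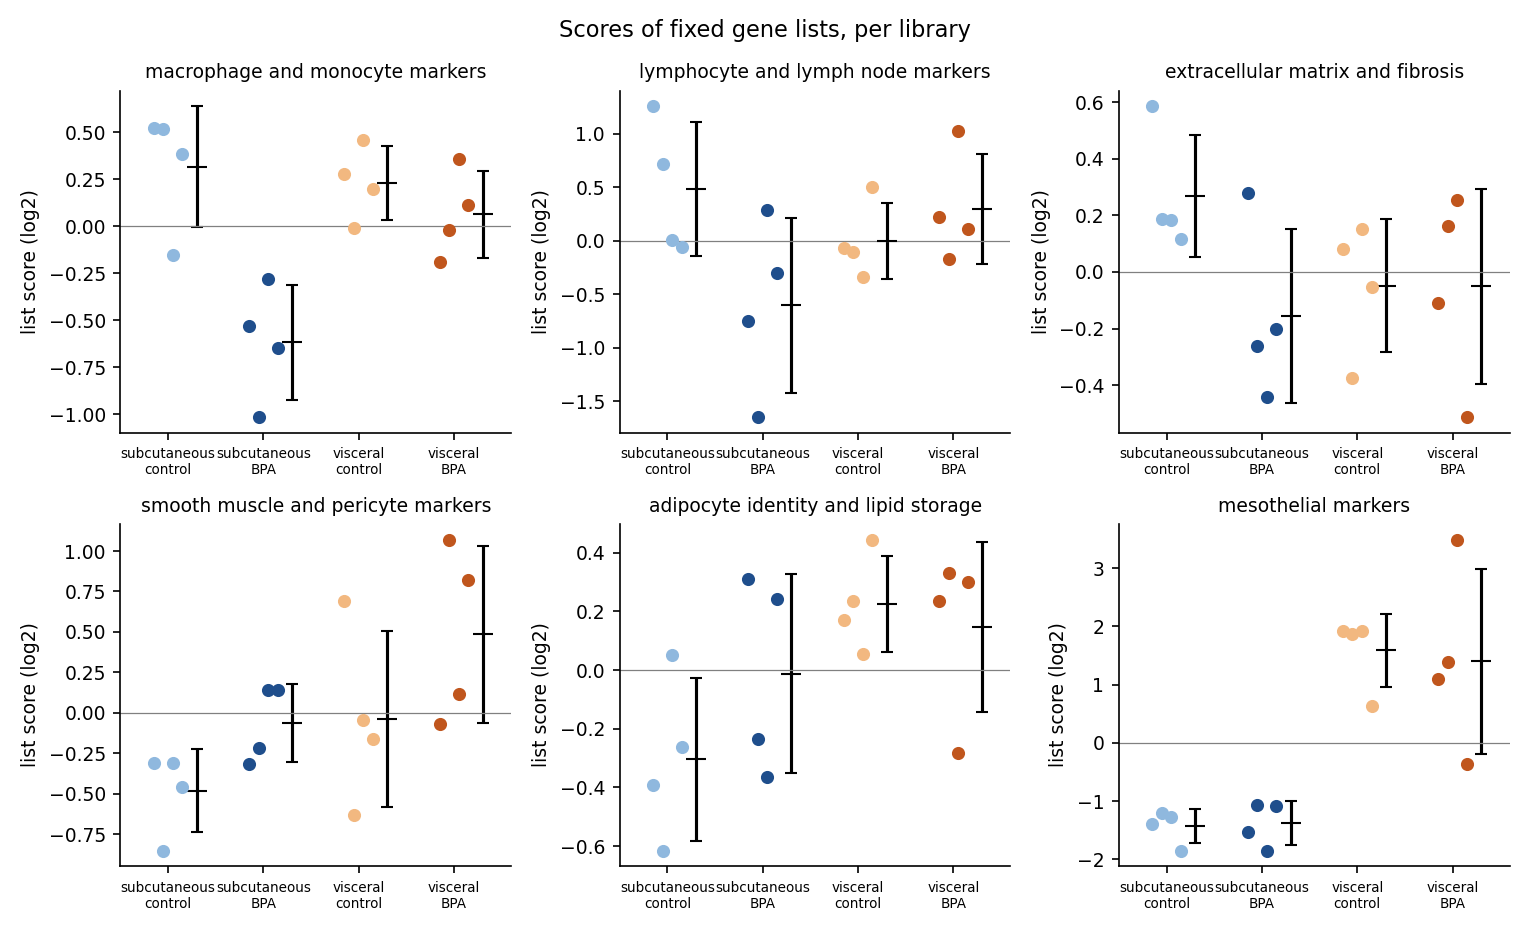
Scores of 6 fixed lists per library, as the median over members of log2 CPM centred on the mean of all 16 libraries. Points are libraries and bars are group means with SD (n = 4). The adipocyte score of visceral BPA replicate 977 is -0.284 and the matrix score of subcutaneous control 902 is 0.587.

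The comparison of visceral with subcutaneous fat in control animals describes the unexposed difference between depots. Homeobox and mesothelial genes, HOXA9 and WT1 among them, had some of the largest folds. Mesothelial and adipocyte lists were higher in visceral fat at the preset correlation (7 of 11 and 7 of 25 genes called higher), but not with an estimated one (adjusted p = 0.219 and 0.36). COL1A1, COL1A2 and COL6A3 were higher in subcutaneous fat. edgeR called 1928 of 14456 genes, 1037 higher and 891 lower in visceral fat, with 4271 at an unadjusted p under 0.05 where 723 would be expected. Groups did not overlap for 1740 of the called genes and for 19.8% of all tested, against a chance share of 2.86%. In visceral fat, TCF21, a transcription factor of visceral mesenchyme, was at least 83.4-fold higher (10.7 ± 1.19 CPM against no count; adjusted p = 0.000154). LRRN4, a mesothelial surface protein, was at least 193-fold higher (adjusted p = 0.000273). NKX3-2, a homeobox gene of gut mesenchyme, had 18.2 ± 3.35 CPM against 1 count in all subcutaneous controls, a ratio of 429 (interval 76.9 to 16980; adjusted p = 7.77e-06). WT1, a mesothelial transcription factor, had 18.3 ± 2.77 CPM against 1 count (ratio 428, interval 76.6 to 16920), and BNC1 17.2 ± 6.96 CPM against 3 counts (133, 45.3 to 646). LOC101103644, without a symbol, had 46.3 ± 18.2 CPM against 3 counts (355, 121 to 1725). ADRB1 and ADRB3, the beta-adrenergic receptors of fat cells, were 4.56-fold and 16.2-fold higher (adjusted p = 0.00151 and 0.00359). UPK3B, a mesothelial uroplakin, was 22.5-fold higher (0.00023).

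Genes higher in subcutaneous fat of controls include IRX2, HOXA10, HOXA9, PITX1, IRX1 and HOXC9, all homeobox genes. IRX2 was at least 409-fold lower in visceral fat (27.0 ± 12.2 CPM against no count; adjusted p = 0.00027), HOXA10 at least 90.0-fold (0.00187), and LGR5, a Wnt co-receptor, at least 57.0-fold (0.00207). HPSE2 (LOC114110341), a heparanase-like protein, was at least 54.6-fold lower (0.0015). HOXA9 had 33.1 ± 8.29 CPM against 1 count in visceral fat (ratio 1525, interval 273 to 60300; adjusted p = 2.2e-06), and PITX1, a hindlimb homeobox gene, 11.4 ± 4.19 CPM against 1 count (530, 94.4 to 21020). IRX1 fell by 8.73 ± 0.59 on the log2 scale (adjusted p = 1.78e-05), HOXC9 by 3.77 ± 0.28 (3.52e-05) and TBX15, a limb and trunk regulator, by 3.22 ± 0.21 (1.38e-05). CXCL14, a chemokine, fell by 5.91 ± 0.80 (0.00149), and LOC114109061, unmatched, was 147-fold lower (0.0015). COL1A1 fell by 1.82 ± 0.22, from 1767 ± 305 to 502 ± 137 CPM (0.000856), COL1A2 by 1.90 ± 0.22 (0.000641), and COL6A3 by 1.30 ± 0.19 (0.0022).

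Of the 29 control depot lists tested, 13 were called. Depot developmental genes had a median of -0.83, the same with genes at 0 set at their bound (camera adjusted p = 3.12e-06, adjusted p = 0.0454 with an estimated correlation), with 1 of 27 higher and 13 lower, and 15 adjusted over the list alone. Mesothelial markers had 2.97, the same at the bound (5.13e-06, adjusted p = 0.219 with an estimated correlation), with 7 of 11 higher and 1 lower, and 8 adjusted over the list alone. Adipocyte genes were higher in 24 of 25 (0.48; 1.32e-05, adjusted p = 0.36 with an estimated correlation), with 7 higher and 8 adjusted over the list alone. They include PPARG (1.92-fold, adjusted p = 0.00568), LPL, lipoprotein lipase (3.01-fold, 0.00722), DGAT2, the last step of triglyceride synthesis (4.44-fold, 0.0158), and ADIPOQ (1.94-fold, from 5556 ± 1574 to 10770 ± 2378 CPM, 0.0286). Fatty acid synthesis genes had 0.41 (0.0114, adjusted p = 0.57 with an estimated correlation; 5 of 19 higher, 8 adjusted over the list alone), among them GPAM (2.86-fold), LPIN1 (2.71-fold) and MLXIPL (1.63-fold). Respiratory chain genes had 0.28 (0.000166, adjusted p = 0.726 with an estimated correlation; 4 of 68 higher, 2 adjusted over the list alone), with ATP5PF, an ATP synthase subunit, 1.96-fold higher. Ribosomal proteins had 0.26 (0.000661, adjusted p = 0.769 with an estimated correlation; 5 of 76 higher, 2 adjusted over the list alone).

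Oxidative stress genes in controls had 0.40 (0.00351, adjusted p = 0.36 with an estimated correlation; 4 of 21 higher, 6 adjusted over the list alone), with SOD2, mitochondrial superoxide dismutase, 1.59-fold higher (0.035) and PRDX6, a peroxiredoxin, 1.73-fold (0.0398). Immediate early genes had 0.27 (0.00631, adjusted p = 0.518 with an estimated correlation; 6 of 24 higher, 7 adjusted over the list alone), with EGR1 3.92-fold and NR4A1 2.598-fold higher. Smooth muscle markers had 0.53 (0.0249, adjusted p = 0.666 with an estimated correlation; 2 of 13 higher, 3 adjusted over the list alone), with SYNPO2, an actin-binding protein, 2.58-fold higher. Proteasome subunits had 0.18 (0.0369, adjusted p = 0.806 with an estimated correlation; 3 of 38 higher, and 3 adjusted over the list alone). Progenitor markers had -0.57 (0.00631, adjusted p = 0.36 with an estimated correlation; 4 of 15 lower, 6 adjusted over the list alone), with CD34 and PDGFRB, surface proteins of stromal cells, lower by 1.78-fold and 1.82-fold. Clock genes had -0.24 (0.0114, adjusted p = 0.36 with an estimated correlation; 2 of 17 lower, and 2 adjusted over the list alone), with BHLHE40 2.48-fold and CRY2 2.002-fold lower. Matrix genes had -0.33 (0.0251, adjusted p = 0.708 with an estimated correlation; 2 of 26 higher and 6 lower, and 8 adjusted over the list alone), BGN, biglycan, being 2.54-fold higher.

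The other 16 depot lists in controls were not called (adjusted p from 0.0675 to 0.724). They are endothelial, lymphocyte, thermogenic, snRNA, chromatin, cholesterol, skeletal muscle, macrophage, nerve, interferon, insulin signalling, snoRNA, cell cycle, endoplasmic reticulum stress, cytokine and steroid receptor genes. The snoRNA list had a median of 0.014 and a test in the lower direction, and the steroid receptor list -0.018 and the higher direction. Single members still changed. KDR and FLT1, receptors of vascular growth factor, were 2.09-fold and 2.16-fold higher, RGS5, of pericytes, 2.53-fold, and MRC1, a macrophage receptor, 1.80-fold. ADGRE1 (LOC101107096), of macrophages, was 5.30-fold lower, and JCHAIN, of plasma cells, 7.39-fold (log2 -2.886, and -1.181 without subcutaneous 902 and 924). Of the genes named whatever their result, INSR had log2 0.41 ± 0.16 (0.125), SCD -1.51 ± 0.63 (0.139; -0.533 without subcutaneous 928), LEP 0.86 ± 0.39 (0.167), FASN -0.56 ± 0.37 (0.345), CD68 0.13 ± 0.29 (0.809) and ESR1 0.02 ± 0.21 (0.967).

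With the animal number as a random block in limma voom on 16 libraries, 2348 genes were called between depots in controls, against 1510 by voom without it. A fixed block in edgeR on shared numbers, which leaves out visceral 908 and subcutaneous 931, called 2615. These fits change the test or the libraries as well as the block. The voom fit with the block did not call BNC1 (adjusted p = 0.0868; 2.22e-12 to 0.111 over its alternatives), MLXIPL (0.0746; 0.00132 to 0.114), EGR1 (0.0643; 6.94e-07 to 0.105), NR4A1 (0.0793; 3.24e-05 to 0.246) or MRC1 (0.0885; 0.00113 to 0.134). Of 56 named genes it ended 5 calls and voom without the block 9, so these losses cannot be credited to the block. The list test with the block on 16 libraries did not call matrix (0.0822; 0.012 to 0.708) or immediate early genes (0.0555; 0.000531 to 0.518). The fixed-block fit did not call SOD2 (0.0736; 0.00949 to 0.173). It called LEP, SCD, FASN and CD68 at adjusted p of 0.00956, 0.00223, 0.023 and 0.0167, each the lowest of its alternatives, whose highest were 0.368, 0.497, 0.728 and 0.995. The count was 1245 without visceral control 902, 1216 without 908, 1043 without 928 and 1239 without subcutaneous control 924. Of 50 called genes examined singly, 42 were called in every omission of 1 library. Those that were not include ADIPOQ, GPAM, LPIN1, MRC1, PDGFRB, PRDX6 and SOD2, with highest adjusted p of 0.0857, 0.0705, 0.063, 0.0601, 0.0583, 0.114 and 0.0894. Omission of visceral 902, 908, 924 or 928 ended 4, 7, 1 and 8 of these calls, and of subcutaneous 902, 924, 928 or 931 it ended 4, 6, 3 and 2.

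List calls between depots in controls that were lost when 1 library was left out were as follows. The smooth muscle call was lost without visceral 902 (adjusted p = 0.154) or subcutaneous 924 (0.0821), and the ribosomal call without visceral 908 (0.054) or subcutaneous 924 (0.108). The matrix call was lost without visceral 908 (0.054) or subcutaneous 902 (0.159), and the fatty acid synthesis call without subcutaneous 931 (0.0719). The proteasome call was lost without visceral 908 (0.25) or 928 (0.0723), or subcutaneous 902 (0.0676) or 924 (0.618). Without subcutaneous 902 and 924 together, 8 of the 13 calls remained, and the respiratory chain call was also lost (0.184).

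**Figure D5:**
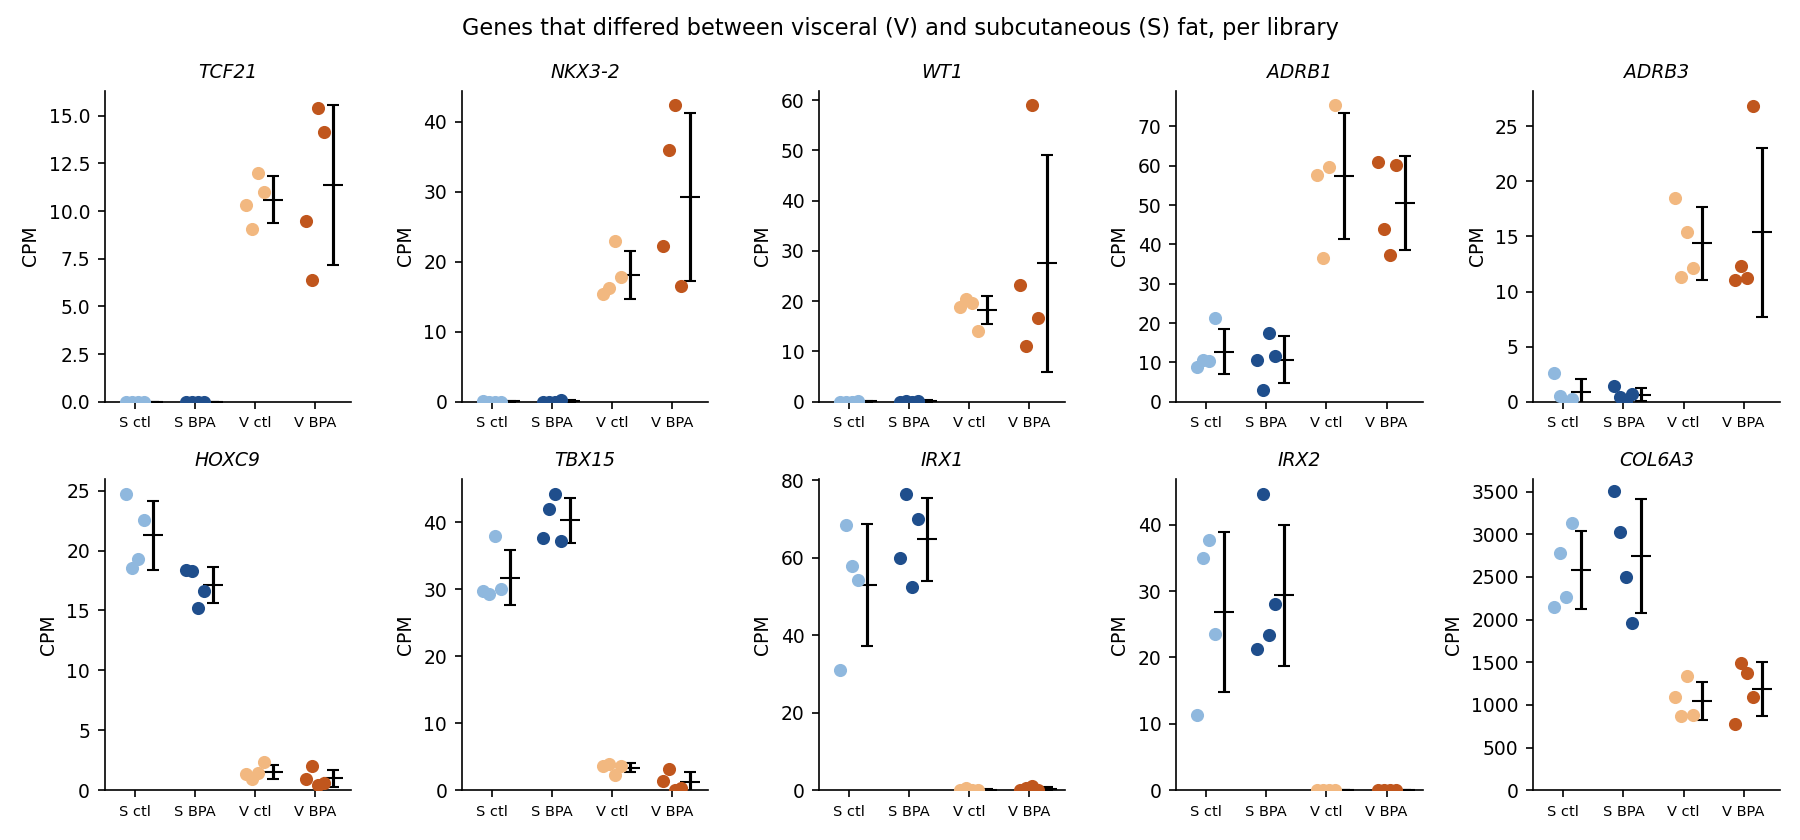
CPM per library of 10 genes that differed between visceral (V) and subcutaneous (S) fat. Points are libraries and bars are group means with SD (n = 4), on axes that start at 0. TCF21, NKX3-2 and WT1 are near 0 in subcutaneous fat, and IRX1 and IRX2 near 0 in visceral fat, in control and BPA animals.

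In BPA animals, TCF21, NKX3-2, WT1, IRX1, IRX2, HOXA9 and HOXC9 again differed between the depots. The macrophage list was higher in visceral fat at the preset correlation, with 4 of 18 markers called, but not with an estimated one (adjusted p = 0.422). edgeR called 1250 of 13782 genes, 707 higher and 543 lower in visceral fat, with 3718 at an unadjusted p under 0.05 where 689 would be expected. The balance of directions was not stable: the replicate block gave 1047 higher and 1253 lower, voom 886 and 1085, and quantile normalization 678 and 696. A fixed block on the 2 shared numbers moved it the other way, to 611 higher and 310 lower, and 462 of these 921 genes were among the 1250. That fit holds only the 4 libraries of these numbers, and whether they are pairs is open. Groups did not overlap for 1170 of the called genes and for 18.6% of all tested, against a chance share of 2.86%. KRT23, a keratin, was at least 88.9-fold higher in visceral fat (15.6 ± 4.95 CPM against no count; adjusted p = 0.0012), TCF21 at least 64.9-fold (0.00236), LRRN4 at least 209-fold (0.0196) and LOC101103644 at least 183-fold (0.0106). NKX3-2 had 29.3 ± 12.1 CPM against 1 count (ratio 462, interval 82.7 to 18260; adjusted p = 0.000296), WT1 27.6 ± 21.8 CPM against 2 counts (209, 57.8 to 1731; 0.00138), and GATA5, a mesodermal factor, 16.7 ± 22.0 CPM against 3 counts (74.6, 25.4 to 363; 0.0138). ADRB3 and ADRB1 were 22.0-fold and 4.77-fold higher (0.00331 and 0.0105). These means lean on visceral 977, with 49.084 CPM of GATA5, 58.961 of WT1, 106.699 of LRRN4 and 78.864 of LOC101103644, against at most 8.312, 23.304, 21.065 and 25.165 in the other 3 (scaled over 16 libraries). All 4 genes were still called without it. IRX2 was at least 370-fold lower in visceral fat (adjusted p = 0.000296) and HPSE2 (LOC114110341) at least 64.6-fold (0.00292). LOC105613955, a long non-coding RNA, had 4.05 ± 1.44 CPM against 1 count (ratio 156, interval 27.2 to 6263). IRX1 fell by 7.65 ± 0.61, EN1, a homeobox gene of trunk skin, by 5.62 ± 0.47, HOXA9 by 5.33 ± 0.74, HOXC9 by 4.08 ± 0.42 and FRMPD4 by 6.28 ± 0.82.

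Of the depot lists in BPA animals, 13 of 29 were called. Macrophage markers were higher in 17 of 18, by a median of 0.83 (camera adjusted p = 9.86e-05, adjusted p = 0.422 with an estimated correlation), with 4 called and 7 adjusted over the list alone. CD68 was 2.31-fold higher (50.3 ± 9.15 against 21.8 ± 1.86 CPM; adjusted p = 0.00492), FCER1G, an immune receptor subunit, 2.96-fold (0.00553), TYROBP 2.96-fold (0.0165) and CD14, an endotoxin receptor, 1.93-fold (0.0273). Depot developmental genes had -0.69, as with genes at 0 at their bound (2e-06, adjusted p = 0.366 with an estimated correlation; 1 of 26 higher and 12 lower, 15 adjusted over the list alone). The snRNA list had -1.19 (8.63e-07, adjusted p = 0.422 with an estimated correlation; 7 of 23 lower, 9 adjusted over the list alone). The snoRNA list had -0.48 (2e-06, adjusted p = 0.678 with an estimated correlation; 1 of 158 higher and 13 lower, 16 adjusted over the list alone). Ribosomal proteins had 0.35 (2e-06, adjusted p = 0.612 with an estimated correlation; 9 of 76 higher, 14 adjusted over the list alone), with RPS6 1.99-fold and RPL26 2.23-fold higher. Immediate early genes had 0.96 (8.98e-05, adjusted p = 0.571 with an estimated correlation; 1 of 23 higher, 3 adjusted over the list alone), with HSPH1, a chaperone, 3.62-fold higher (log2 1.855, and 0.916 without visceral 984). Clock genes had -0.48 (0.00254, adjusted p = 0.422 with an estimated correlation; 3 of 17 lower, 4 adjusted over the list alone), with CRY2 and PER3 2.44-fold and 2.24-fold lower.

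Oxidative stress genes in BPA animals had 0.41 (0.00403, adjusted p = 0.571 with an estimated correlation; 4 of 21 higher, and 4 adjusted over the list alone), with GPX1 2.21-fold, GPX3 2.62-fold and HMOX1, heme oxygenase, 2.01-fold higher. Smooth muscle markers had 0.72 (0.0262, adjusted p = 0.571 with an estimated correlation; 1 of 13 higher, 7 adjusted over the list alone). Lymphocyte markers had 0.85 (0.0262, adjusted p = 0.61 with an estimated correlation; 1 of 12 higher, 2 adjusted over the list alone). Endothelial markers had 0.29 (0.0397, adjusted p = 0.571 with an estimated correlation; 3 of 16 higher, and 3 adjusted over the list alone), with ENG 2.28-fold and KDR 1.91-fold higher. Nerve markers had 0.73 (0.0465, adjusted p = 0.571 with an estimated correlation; 2 of 8 higher, and 2 adjusted over the list alone), with SOX10, of Schwann cells, 7.81-fold higher. Mesothelial markers had 1.89, the same at the bound (0.047, adjusted p = 0.571 with an estimated correlation; 2 of 6 higher, 5 adjusted over the list alone). The other 16 lists were not called (adjusted p from 0.0602 to 0.963). They are cytokine, cholesterol, insulin signalling, progenitor, adipocyte, respiratory chain, skeletal muscle, thermogenic, endoplasmic reticulum stress, fatty acid synthesis, steroid receptor, cell cycle, matrix, interferon, proteasome and chromatin genes. Among their members, MMP2, a matrix protease, was 5.25-fold lower, COL6A3 2.32-fold, CD34 1.79-fold and PDGFRB 2.33-fold lower. BGN was 3.19-fold higher, IGF1 2.78-fold, CFD, complement factor D, 2.46-fold and DHCR7, of cholesterol synthesis, 9.28-fold higher. FASN had log2 -1.31 ± 0.38 (adjusted p = 0.0559), PPARG 0.64 ± 0.23 (0.101), LEP 1.37 ± 0.63 (0.186; 0.546 without visceral 910), SCD -1.14 ± 0.54 (0.199; -0.339 without subcutaneous 922) and ADIPOQ 0.64 ± 0.31 (0.205). ESR1 had -0.50 ± 0.32 (0.343), COL1A1 0.34 ± 0.56 (0.742; -0.562 without visceral 977) and INSR 0.09 ± 0.22 (0.823).

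Every omission of 1 library moved the depot count in BPA animals by more than 1.5 times. It was 815 without visceral 910, 792 without 918, 2206 without 977 and 818 without 984. It was 726 without subcutaneous 918, 369 without 922, 491 without 941 and 719 without 977. Of 45 called genes examined singly, 30 were called in every omission that tested them. Without visceral 918, 977 or 984, 44 of the 45 were tested. Calls lost were 7 without subcutaneous 918 (highest adjusted p 0.103), 14 without 922 (0.132), 12 without 941 (0.112) and 7 without 977 (0.0987). They were 7 without visceral 910 (0.0937), 4 without 918 (0.094), 6 without 984 (0.0866) and 0 without 977. The 15 are CD14, CD34, COL6A3, CRY2, ENG, GATA5, GPX3, HMOX1, HSPH1, KDR, LRRN4, PDGFRB, PER3, RPL26 and SOX10.

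List calls in BPA animals that were lost when 1 library was left out were these. The endothelial call was lost without visceral 918 (adjusted p = 0.0979) or subcutaneous 918 (0.0712), 922 (0.0507) or 941 (0.0549). The mesothelial call was lost without visceral 918 (0.0956) or 977 (0.0842), and the smooth muscle call without visceral 918 (0.142) or subcutaneous 918 (0.0549). The nerve call was lost without visceral 918 (0.166), 977 (0.173) or 984 (0.124), or subcutaneous 918 (0.0549) or 922 (0.0739). The lymphocyte call was lost without visceral 977 (0.173) or subcutaneous 922 (0.093).

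The depot differences of control and BPA animals overlapped. Among 13657 genes tested in both, 992 and 702 were called higher in visceral fat, 417 of them in both sets, where 51 would be expected if the sets were independent. For genes lower in visceral fat the counts were 846 and 526, with 273 in both and 32.6 expected. No gene was called in opposite directions, and the log2 fold changes had a Pearson r of 0.724 across genes, which are not independent replicates.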

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

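Of the tests in this part, 4 were chosen only after the result was seen: the share against the library total, lymphoid tissue in subcutaneous controls 902 and 924, a smaller share of all cells other than adipocytes, and mesothelium in visceral BPA replicate 977. The fit with the library total as a covariate was also added after the data were seen. The other tests were set before their own results were seen, though thinning was chosen after the calls of short genes were known. A library was singled out when its gap to the nearest of its group, as a share of the group's range, was above Dixon's 95% limit for 4 libraries. This held in 48 of 557 groups examined, where chance gives about 1 in 20, or 27.9.

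Of 202 genes under 200 bases tested, 72 were called higher in subcutaneous fat of BPA animals, while the snoRNA and snRNA lists did not pass with an estimated correlation (adjusted p = 0.234 and 0.118). Unequal counts at the test did not alone make these calls, since 44 were still called higher after every library was thinned to the lowest total. Thinning keeps each library's share of short genes, so it cannot test a cause tied to how a library of low total was made. Intron reads of host genes stay open. Short genes classed as outside longer genes rose by a median of 1.701, against 1.487 for those classed as inside. The build behind the counts is unknown, so these classes are uncertain and cannot decide it. Better recovery of short fragments stays open: the Spearman correlation of fold change with length was -0.129 over 202 genes (permutation p = 0.0686, two-sided). A share that falls with the library total also stays open, since its slope within the other 3 groups predicts 0.543 of the rise (interval 0.195 to 0.89), or 0.357 without visceral BPA 977 (-0.095 to 0.809). With the library total as a covariate 13 genes were called in place of 96, 7 of them shared. The 72 short genes then had a median log2 fold change of 1.644 (median SE 0.423) in place of 2.218 (0.337), and 5 were called, since estimates shrank and SEs widened. These 72 were picked for having been called. Over all 202 short genes tested the median was 1.091 in place of 1.555, with 184 higher. Library preparation and prenatal BPA cannot be told apart here, because subcutaneous BPA is also the group with the lowest mean depth, and an effect of BPA remains untested.

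The macrophage list was lower in subcutaneous fat of BPA animals at the preset correlation, with 1 of 18 markers called, but not with an estimated one (adjusted p = 0.148), so the fall itself is unsettled. Lymphoid tissue in controls 902 and 924 is argued against as the whole cause, since the median log2 fold change was -0.79 without both libraries. Only controls 928 and 931 remain there, with macrophage scores of -0.154 and 0.383, and BPA 941 scored -0.28. The argument thus rests on few controls, 1 of them close to a BPA library. A smaller share of all cells other than adipocytes stays open, since endothelial, matrix and progenitor lists were also lower at the preset correlation. Smooth muscle and macrophage scores moved apart, in a contrast chosen after the smooth muscle list was seen higher and the macrophage list lower. The lowest BPA library lay 0.367 above the highest control in the difference of these scores (0.554 ± 0.29 against -0.801 ± 0.498, SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow). For endothelial minus macrophage scores the groups overlapped (exact two-sided permutation p = 0.0857). Fewer macrophages or lower expression in them after prenatal BPA stay open as untested hypotheses.

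Visceral BPA replicate 977 lay far from its group in several measures. It had 16926 genes with a count, an adipocyte score of -0.284, a respiratory chain score of -0.382 and an immunoglobulin segment share of 0.0379%. Its CPM was 25.29 for UHRF1, 23.794 for EZH2, 2780.303 for FN1, 106.699 for LRRN4, 49.084 for GATA5 and 23.195 for SHANK1. Though not singled out by the limit, it also had the lowest visceral total (6.77 M) and the highest visceral share of genes under 200 bases (1.1285%). Its lymphocyte score (1.022) was the highest in visceral fat as well. Whether preparation or lymphoid cells set it apart was not tested. Depth is argued against for the number of genes, since the other 3 libraries thinned to its total still had at least 17223. More mesothelium in the tissue piece stays open: pooled mesothelial markers had 456.4 CPM, against 71.7 to 256.8 in the other visceral libraries, and of 10 markers at 10 CPM or more, 7 exceeded every other visceral library. LRRN4, BNC1 and WT1 had 107, 60.5 and 59.0 CPM, while PRG4, GPM6A and CDH3 were at 34.6, 27.7 and 14.5, below the highest other library (61.9, 44.9 and 18.6). The list names 16 markers, 15 of them in the table and 0 of these in another list, and no biological explanation other than mesothelium was tested.

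In visceral BPA replicate 918, MYH11 (2262.878 CPM) and DES (278.291) were far above the group and the 1 count of LOC105613955 in visceral BPA fat lay there (0.114). In visceral BPA 984, ADRB3 (26.885), HMOX1 (41.194) and HSPH1 (302.44) were far above, and in visceral BPA 910 DHCR7 (9.812). Visceral control 902 was apart in DES (51.218) and FMOD (13.272), and control 908 in LAPTM5 (36.802), INSR (592.526), HOXA9 (0.095) and IRX1 (0.473). Visceral control 924 was apart in PITX1 (0.086) and TBX15 (2.328), and control 928 in its mesothelial score (0.636), BGN (210.626) and CXCL14 (0.407).

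Subcutaneous control 902 was apart in its matrix score (0.587), LEP (562.434 CPM), TRNAR-CCU_7 (0.311) and NKX3-2 (0.156), and control 928 in THY1 (66.451), LGR5 (7.209), TBX15 (37.927) and BNC1 (0.47). Subcutaneous control 931 was apart in its share of short genes (0.4593%) and of snoRNA genes (0.3718%), WT1 (0.205 CPM) and ADRB1 (21.281). Subcutaneous BPA 918 was apart in NFKBIA (57.07), COL1A1 (1254.102) and HSPH1 (46.151), BPA 922 in LPIN1 (433.691) and BPA 941 in CD68 (24.319). BPA 977 was apart in FBN1 (798.936), NKX3-2 (0.224) and SOX10 (1.794). For NKX3-2, WT1, HOXA9, PITX1, BNC1, CXCL14 and LOC105613955 the value rests on a handful of counts in a group otherwise near 0.

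At the preset correlation 11 lists were called for a BPA effect that differs between depots, but 0 with an estimated correlation (smallest adjusted p 0.0972). The median over members of the visceral minus the subcutaneous log2 effect was -0.302 for adipocyte, 0.35 for matrix, 0.645 for immediate early, 0.412 for cytokine, 1.46 for lymphocyte and 0.89 for macrophage genes. It was -0.155 for respiratory chain, -0.121 for proteasome, -0.573 for snoRNA, -0.962 for snRNA and -0.153 for steroid receptor genes.

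Other splits of the libraries were compared with the real one. In subcutaneous fat, BPA against control gave 96 genes and the highest other split 1, so 1 of 35 splits gave as many. That is the smallest share these splits allow, and it is not adjusted over the comparisons. Its 14 lists were also reached in 1 of 35 splits, but the highest other split called 13, and 0 lists passed with an estimated correlation. Between depots in controls the real split gave 1928 genes and the highest other 0 (1 of 35). Only 8 of these splits part all 3 pairs of libraries, as the real one does, and the others keep at least 1 pair together, so these splits are too few to give a share under 0.05. Its 13 lists were reached in 3 of 35 splits, or 2 of 8 (highest other 17). In BPA animals it gave 1250 and the highest other 2 (1 of 35). If the 2 shared numbers there are pairs, only 12 splits part both, again too few. Its 13 lists were reached in 4 of 35 splits, or 2 of 12 (highest other 14). Chance cannot be excluded for the number of lists in visceral BPA against control (6; 25 of 35, highest other 14). For the difference between BPA effects it cannot be excluded for 11 lists (32 of 95, highest other 15) or the correlation of 0.282 (16 of 95, highest other 0.388). Where 0 genes were called, every split gives as many by construction, so the splits are uninformative for visceral BPA against control (35 of 35, highest other 2) and for the difference (95 of 95, highest other 1).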

How the results depend on the processing

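Alternatives chosen only after the data were seen were thinning, voom without a block, omission of subcutaneous controls 902 and 924 together, omission of genes under 200 bases, and the library total as a covariate. Of values for single genes, 937 of 1163 in subcutaneous BPA against control kept their direction and their side of the threshold, 185 kept the direction but were no longer called, 32 became called and 9 turned in direction. In visceral BPA against control 685 of 699 were the same, between depots in controls 1129 of 1222, in BPA animals 1007 of 1118, and for the difference between effects 859 of 867. The median fold change of all genes moved by more than 0.1 only without scaling, to -0.1471 between depots in controls and -0.1012 in BPA animals. Pseudocounts of 0.5 and 5 were not run, since the count test uses none. Library weights were run through voom.

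The subcutaneous BPA count of 96 was 173 without a filter, 54 with at least 50 counts, 56 with library weights, 464 by DESeq2, 216 at a threshold of 0.10, 46 with all 16 libraries, 1 with the replicate block, 1 by voom without it and 60 thinned. It was 0 by edgeR without controls 902 and 924, 1 without genes under 200 bases, 13 with the library total, and 32 to 128 with each library omitted. Fewer genes tested and fewer libraries enter some of these, and the cause was not tested for the others. Between depots in controls the count was 3062 at 0.10, 1045 thinned, 1138 without controls 902 and 924, and 1043 to 1755 with each library omitted. In BPA animals it was 2197 by DESeq2, 2312 at 0.10, 2408 with all 16 libraries, 2300 with the block, 1971 by voom, 761 thinned and 369 to 2206 with each library omitted. DESeq2 called 5 genes in visceral BPA against control and 11 for the difference between effects, where edgeR called 0 (1103 and 917 at an unadjusted p under 0.05). Thinned counts have less depth by construction, so depth limits how many genes are called. The correlation of BPA effects was 0.111 with visceral-only animals, 0.24 with subcutaneous-only animals, and 0.22 to 0.341 with each library omitted. With an estimated correlation 0 lists were called in visceral and 0 in subcutaneous BPA against control, 1 between depots in controls, 0 in BPA animals and 0 for the difference. In visceral BPA against control 5 to 10 lists were called with each library omitted, and with at least 50 counts 8 were called between depots in BPA animals.

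Direction turned for these values, none of them called, except the proteasome list, and the cause was not tested. Proteasome subunits had -0.053 between depots in controls and 0.042 for the difference without controls 902 and 924. In visceral BPA against control, ADIPOQ had 0.058 with quantile normalization, SCD 0.049 with the block and CD68 -0.069 thinned. In subcutaneous fat, ADIPOQ had -0.033 with quantile normalization, -0.004 with the block, -0.024 by voom and -0.14 without controls 902 and 924, and SCD 2.221 with the library total. Between depots in controls, ESR1 had -0.043 with quantile normalization, -0.012 with at least 50 counts, -0.028 with weights, -0.01 with the block and -0.155 with shared numbers, and CD68 -0.218 without controls 902 and 924. In BPA animals, INSR had -0.136 with quantile normalization, -0.017 with the block and -0.361 with shared numbers, and COL1A1 -0.291 with quantile normalization, -0.281 with weights and -0.075 by voom. For the difference, ADIPOQ had 0.137 with quantile normalization and LEP -0.197 without controls 902 and 924.

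With each library omitted in turn, PPARG ranged from -0.291 to 0.091, SCD from -0.319 to 0.114, INSR from -0.31 to 0.047 and CD68 from -0.043 to 0.163 in visceral BPA against control. In subcutaneous fat ADIPOQ ranged from -0.147 to 0.211 and SCD from -1.249 to 0.512. Between depots in controls ESR1 ranged from -0.144 to 0.196 and CD68 from -0.066 to 0.556. In BPA animals INSR ranged from -0.129 to 0.237 and COL1A1 from -0.562 to 0.66. For the difference LEP ranged from -0.308 to 0.831 and SCD from -0.591 to 1.175.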

Other observations

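Shares of a pair of gene classes that no fixed list covers were compared between depots, in measures per library that were added only after the data were seen, and none passed 0.05 when adjusted. Ribosomal RNA genes took 0.0884 ± 0.0207% of counts in visceral and 0.254 ± 0.0770% in subcutaneous fat of controls (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow; Benjamini-Hochberg 0.103 over 36 measures). In BPA animals the shares were 0.141 ± 0.0506% and 0.302 ± 0.0680% (exact two-sided permutation p = 0.0286). Immunoglobulin segments took 0.00283 ± 0.00163% in visceral and 0.0333 ± 0.0219% in subcutaneous controls (exact two-sided permutation p = 0.0286), and 0.0116 ± 0.0176% and 0.0112 ± 0.00817% in BPA animals (exact two-sided permutation p = 0.971). That visceral BPA mean rests on replicate 977 at 0.0379%, and the other 3 had 0.0048, 0.0018 and 0.0018%. Ribosomal RNA was depleted in preparation, so its share also depends on that step, and depots differed in depth (11.9 ± 0.886 against 5.61 ± 0.728 M counts in controls). The exact tests here treat libraries as independent, though those of 3 control numbers are pairs across depots and some BPA ones may be.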
